A study of Xenopus laevis with 6 samples.

How the data were processed

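Animal caps are the ectoderm at the top of the blastula, which forms epidermis when cultured alone. Per the labels, Xenopus laevis embryos from in vitro fertilization received antisense morpholino oligonucleotides in the animal side of each cell at the 4-cell stage. The doses were 80 ng of a control morpholino, 40 ng each of a pair against ERK3, or 40 ng each of a pair against TFAP2A. Caps were cut out at stage 9 and cultured to stage 15. The labels describe the replicates as biological and independent, and each of the 3 groups had 2 arrays. RNA was extracted with TRIzol, per the labels' protocols. From 250 ng of total RNA, labelled target was made with a GeneChip 3′ IVT kit. The series' design text and the labels' protocols name different versions of that kit.

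The deposited values are probe set intensity values on the GeneChip Xenopus laevis Genome Array 2.0, which the authors made with the robust multiarray average (RMA) in Expression Console, per the series' design text. Scanned images were read with GeneChip Operating Software 1.4, per the same text, and the version of Expression Console is not given in the sources used here. RMA subtracts background, aligns the arrays by quantiles and fits 1 value per probe set, and this alignment can hide a change that most transcripts share. The deposited intensity values ran from 2.51 to 14672 and were therefore on a linear scale. The log2 of each was taken with no added constant. The largest standard deviation over arrays of any log2 quantile from the 1st to the 99th percentile was 0.046, so the arrays had been brought to nearly 1 distribution in that range. Whether other arrays were normalized together with these 6 is not given in the sources used here. Median intensity lay between 23.2 and 24.6 on every array. Arrays have no read depth, and their number, 2 per group, limits the precision.

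The table held 32635 probe sets, of which 96 manufacturer control probe sets were left out and 32539 were tested, 64 reporter-gene probe sets among them. A platform annotation of 2016 gave 1 gene symbol to 15495 tested probe sets, several to 279 and none to 16765. The Entrez identifiers of 15384 of the 1-symbol probe sets matched the RefSeq gene table of assembly Xenopus_laevis_v10.1, which updated 2 symbols. This table was used for names only, and no coordinates are given because no genome build is given in the sources used here. Each of 11303 genes was represented by its brightest probe set among those with a single symbol. Xenopus laevis is allotetraploid, and the L and S copies of a gene (homeologues) were kept as separate genes.

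Log2 values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group over all 6 arrays, 3 residual degrees of freedom and 2.99 prior degrees of freedom. The contrasts were ERK3 MO1/2 minus Control MO, TFAP2A MO1/2 minus Control MO and ERK3 MO1/2 minus TFAP2A MO1/2. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05 with no fold threshold. Where both arrays of a group lay under the lower quartile of their arrays, a floor chosen after the values were seen, a change is given as at least its size against that quartile. Standard errors (SE) are those of limma's moderated fit, so ± after a log2 change is always this SE with 2 arrays per group. The p-values measure the spread between arrays that the labels call biological replicates. Groups, contrasts, the tests of probe sets and gene lists, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined, and tests chosen later are named as such.

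The rule for named genes took the 10 largest rises and 10 largest falls of each knockdown against Control MO. It took 5 of each side for the direct contrast and for calls shared by both knockdowns. Each gene had to be called. Except for the shared calls, both knockdown arrays also had to lie outside the range of the control arrays, or of the other knockdown in the direct contrast. Symbols that are only clone or locus identifiers were passed over. The rule also took the target genes and, from each list, up to 4 members with the smallest adjusted p, of which only those called are named.

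There were 26 fixed gene lists. Junction and epithelial lists covered the tight junction, apical-basal polarity, adherens junction, desmosome and hemidesmosome, keratins and epidermal transcription factors. Cell type lists covered multiciliated cells, ionocytes, goblet and small secretory cells, neural tissue, neural crest and placode, mesoderm and endoderm, and the cement and hatching glands. Pathway lists covered BMP, Notch, Wnt, FGF/MAPK response and immediate early genes, actin and actomyosin, extracellular matrix and integrins, p53 targets and apoptosis, innate immunity, heat shock and unfolded protein response, cell cycle and DNA replication, and early embryo and maternal genes. Oxidative phosphorylation and ribosomal proteins served as comparison lists. Members were matched by symbol after removal of the L or S ending and a final number, so that numbered copies of a gene entered, and the morpholino targets were left out. Lists were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg over 26 lists and 3 contrasts together. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were run beside it.

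Both knockdowns were compared with the same control arrays. In 100 simulated sets, unchanged groups therefore shared simulated control arrays, drawn with the fitted spread and with noise independent between arrays. These sets gave the overlap and covariance that such noise alone produces. They leave out any deviation that same-numbered arrays share. In 100 further sets, the called changes of each knockdown were laid on independently drawn probe sets, a test chosen after the results were seen. The fit was tested on simulated data for ERK3 MO1/2 minus Control MO over 32539 probe sets, with 200 changed probe sets in each of 10 draws. It recovered 46.1% of the 2-fold changes and 96.2% of the 4-fold changes. Of its calls 7.2% were false, and a contrast with no change gave a mean of 1 call per draw. A list shifted by 0.4 was called in 10 of 10 draws, and 0 unshifted lists were called. The simulated genes varied independently of each other, so these draws do not test list calls among correlated genes.

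The alternatives were the replicate number as a block, eBayes with trend and robust settings, cyclic loess on top of the deposited values, and leaving out each array in turn. Further alternatives were probe sets at or above the median level only, a 2-fold minimum, an adjusted p under 0.1, and a fit of the 2 groups compared alone. For genes and lists, the mean over all probe sets of a gene, the estimated correlation and fry were tried. Averaging the L and S copies before the list test was chosen after seeing the data. Probe sets with several symbols, or with none, entered the counts but no gene list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.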

Results

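Gene expression was measured in cultured Xenopus laevis animal caps at stage 15 after knockdown of ERK3 or of TFAP2A. ERK3 is an atypical mitogen-activated protein kinase, and TFAP2A is the AP-2 alpha transcription factor of the embryonic ectoderm. The series title sets both knockdowns beside each other in the context of epithelial architecture. There were 2 arrays with the control morpholino, 2 with the ERK3 pair (ERK3 MO1/2) and 2 with the TFAP2A pair (TFAP2A MO1/2), and 32539 probe sets were tested. Across probe sets, which are not independent replicates, the correlation of log2 values was 0.987 to 0.989 between arrays of the same group and 0.962 to 0.983 between arrays of different groups. The median intensity was 24.6 and 24.1 on the control arrays, 23.8 and 23.2 on the ERK3 arrays, and 24.2 and 23.9 on the TFAP2A arrays. Among the RNA quality controls, the 3′ gapdh control had an intensity of 296.2 and 335.4 in control caps, 42.1 and 84.2 in ERK3 knockdown caps, and 180.5 and 242.5 in TFAP2A knockdown caps. The log2 ratio of its 3′ to its 5′ signal lay between 0.76 and 1.34 on all arrays, that of actin between 10.67 and 11.25, with a 5′ log2 signal of 1.61 to 2.11, and that of ef1a between -1.25 and -0.94.

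Of the targeted genes, tfap2a was measured and ERK3 was not examined, because 0 probe sets carry its symbol mapk6 or that of its paralogue mapk4. Transcript levels of tfap2a.L were 1125.5 and 753.4 in control caps, 1816.6 and 1425.1 in ERK3 knockdown caps, and 1495.2 and 1286.8 in TFAP2A knockdown caps. The changes of tfap2a.L were 0.81 ± 0.23 with ERK3 MO1/2 (adjusted p = 0.0847) and 0.59 ± 0.23 with TFAP2A MO1/2 (adjusted p = 0.171), and neither passed; without Control MO replicate 2 they were 0.52 and 0.30. The S copy, tfap2a.S, rose by 0.89 ± 0.18 in ERK3 knockdown caps (adjusted p = 0.0362), a call that ended without any 1 of the 6 arrays, and its change of 0.24 ± 0.18 in TFAP2A knockdown caps did not pass (adjusted p = 0.471) and was 0.47 and 0.02 without Control MO replicates 1 and 2. A morpholino blocks translation or splicing, so its target's transcript need not fall, and these values do not test the labels.

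In ERK3 knockdown caps the named gene with the largest rise was rpe65.L, which encodes the isomerohydrolase of the visual cycle. It rose from intensities of 5.5 and 5.2, under the lower quartile of the control arrays, to 137.8 and 127.7, at least 20.6-fold against that quartile (limma adjusted p = 0.00701). The histidine ammonia-lyase gene hal.2.L rose by 3.96 ± 0.27 on the log2 scale (SE, 2 arrays per group), the early embryonic POU factor gene pou5f3.3.L by 3.86 ± 0.22 and the chemokine gene cxcl12.L by 3.74 ± 0.23. The glutathione peroxidase gene gpx1.S rose by 3.59 ± 0.25 and the tetraspanin gene tspan4.S, also under that quartile in control caps, by at least 3.03. The largest fall was that of wfdc2.L, which encodes a secreted whey acidic protein domain protein, by 4.56 ± 0.47, from 2002.2 and 2856 in control caps to 61.0 and 167.8 (adjusted p = 0.00919). The germ plasm helicase gene ddx25.L fell by 2.84 ± 0.21, the glutathione S-transferase gene mgst1.L by 2.52 ± 0.31, and the glycolytic enzyme gene gapdh.L by 2.41 ± 0.39, as the gapdh control probe sets also read lower. Over probe sets without a symbol, Xl2.55361.1.A1_at rose at least 52.1-fold against the lower quartile, from 5.5 and 5.3 to 346.2 and 325.9 (adjusted p = 0.00236). It was chosen after its values were seen.

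The other rises named by the rule were those of itgb1bp2.L, lgals4.1.s and ehd2.S, between 2.58 and 3.45, and that of mx1.L, an interferon-induced GTPase gene, of at least 2.48. The other falls were those of fam3a.S, rbm12.L, slfn13.L, kcnk1.S, eps8l3.S and tfdp2.S, of which fam3a.S fell by 2.81 and tfdp2.S, a partner of E2F factors, by 2.41. In all, ERK3 knockdown changed 3443 of 32539 probe sets, 10.6%, with 1460 higher and 1983 lower, and 9057 had an unadjusted p under 0.05. Of 11303 genes, 446 rose and 891 fell. Without Control MO replicate 1 or Control MO replicate 2, limma called 0 probe sets, with 7287 and 6539 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.0519 and 0.0558. The count was 267 without ERK3 MO1/2 replicate 1, 1675 without ERK3 MO1/2 replicate 2 and 2002 without either TFAP2A array.

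**Figure D1:**
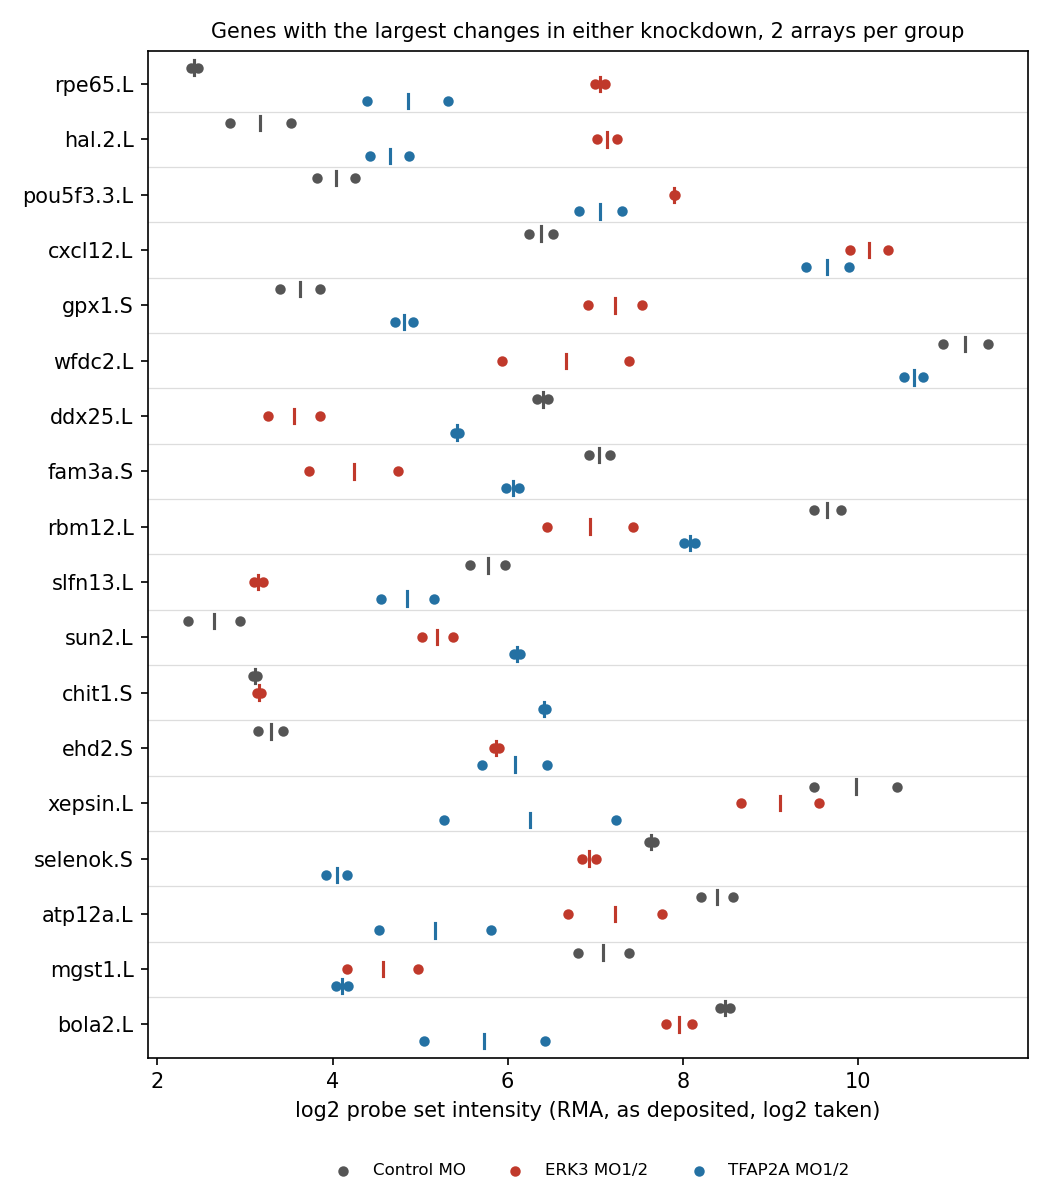
Log2 probe set intensity on the x axis for the genes with the largest changes in either knockdown, with 1 point per array, 2 arrays per group, and a bar at each group mean. For wfdc2.L the ERK3 knockdown arrays lie far below the control and TFAP2A knockdown arrays, and for chit1.S only the TFAP2A knockdown arrays, at 84.4 and 86.4 before log2, stand apart.

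Among epidermal and junction genes in ERK3 knockdown caps, 3 of 26 epidermal transcription factors fell and 1 rose, and the same 3 and 1 resulted when adjusted over the list alone. The Krüppel-like factor genes klf17.1.S and klf17.L fell by 1.85 ± 0.14 and 1.29 ± 0.15, tp63.L, a regulator of the basal epidermis, fell by 1.16 ± 0.16, and prdm1.S rose by 1.25 ± 0.23. In the tight junction list of 28, the claudin gene cldn6.2.S rose by 1.04 ± 0.15 (adjusted p = 0.0161) and was the single member called, also adjusted over the list alone. In apical-basal polarity, the scaffold gene slc9a3r1.L rose and lin7c.L and mark2.L fell, 1 up and 2 down of 19, as adjusted over the list alone. In the adherens junction list of 23, wtip.L fell by 0.66 ± 0.14 and the plakoglobin gene jup.S by 0.54 ± 0.12, and 3 fell adjusted over the list alone. In the list of 13 desmosome and hemidesmosome genes, the periplakin gene ppl.L fell by 1.22 ± 0.17 and itga6.L by 0.98 ± 0.21, with 4 down adjusted over the list alone. Of 29 keratins, krt18.1.L and krt18.3.L fell by 1.10 ± 0.20 and 1.11 ± 0.24, and 2 fell adjusted over the list alone. None of these 6 lists was called by camera, with adjusted p between 0.175 and 0.977, and the gene calls ended without either control array.

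The multiciliated cell list was called lower in ERK3 knockdown caps, with a median change of -0.43 (camera adjusted p = 0.000636), and was not called with an estimated correlation (adjusted p = 0.969) or by fry (0.246). Of 57 measured genes, 9 fell, 1 rose and 47 did not pass, and 17 fell and 1 rose adjusted over the list alone. The cilia genes cfap36.L, cfap126.L, cfap45.L and ccdc78.S fell by 1.89 ± 0.19, 1.48 ± 0.20, 1.46 ± 0.18 and 1.38 ± 0.16. Of 43 ionocyte genes, 6 fell, also adjusted over the list alone, among them tfcp2l1.L, a regulator of these cells, by 1.12 ± 0.18. Of 18 goblet and small secretory genes, agr2.L and agr2.S fell by 2.37 ± 0.51 (-1.58 without ERK3 MO1/2 replicate 1, adjusted p = 0.0744) and 1.69 ± 0.21, and 1 rose and 5 fell adjusted over the list alone. Both copies of agr2 are also among the 3 of 9 cement and hatching gland genes that fell, with ag1.S, which fell by 2.23 ± 0.34, and 4 fell adjusted over the list alone. No other list of the 26 was called in this comparison, with 9 lists in all at an unadjusted camera p under 0.05, and the gene calls ended without either control array.

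Among genes of other lineages, 8 of 70 mesoderm and endoderm genes fell and 1 rose in ERK3 knockdown caps, and 10 fell and 1 rose adjusted over the list alone. The growth factor gene fgf8.L fell by at least 1.16, wnt8a.L fell by 1.22 ± 0.18, and cdx1.S fell by 1.65 ± 0.29. Both copies of Brachyury, a marker of the mesoderm, were lower: tbxt.L fell by 2.18 ± 0.44 and tbxt.S, chosen after its values were seen, fell by 1.91 ± 0.33. Of 29 neural crest and placode genes, sox8.L, ets1.S and pax3.L fell, sox8.L by 1.56 ± 0.12, and 4 fell adjusted over the list alone. Of 49 neural genes, the tubulin gene tubb2b.S fell by 1.38 ± 0.17, and 1 fell adjusted over the list alone. The adjusted p of these 3 lists was 0.150, 0.175 and 0.737, and the gene calls ended without either control array.

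In TFAP2A knockdown caps the named gene with the largest fall was xepsin.L, an epidermal serine protease gene, which fell by 3.72 ± 0.69 from intensities of 725.6 and 1397.8 to 38.6 and 150.9 (limma adjusted p = 0.0269). Its change was -2.74 without TFAP2A MO1/2 replicate 1 and -4.70 without replicate 2, and its call was lost there (0.0700 and 0.0547) and without either control array (0.0713 and 0.139). The endoplasmic reticulum selenoprotein gene selenok.S fell by 3.59 ± 0.14 (adjusted p = 0.0027), the proton-potassium pump gene atp12a.L by 3.22 ± 0.51 and mgst1.L by 2.98 ± 0.31. The antiproliferative gene btg2.S fell by 2.43 ± 0.54 and the circadian repressor gene cry1.L by 2.42 ± 0.17. The nuclear envelope gene sun2.L rose by 3.46 ± 0.23 and the chitinase gene chit1.S by 3.30 ± 0.12, from 8.8 and 8.5 to 84.4 and 86.4 (adjusted p = 0.00268). Rises of cxcl12.L and pou5f3.3.L were 3.27 ± 0.23 and 3.02 ± 0.22, and the glycolytic gene pgk1 rose 5.64-fold. Over probe sets without a symbol, Xl2.48266.1.A1_a_at rose by 5.92 (adjusted p = 0.00588), from 13.7 and 7.0 to 561.9 and 627.9, and was chosen after its values were seen.

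The other named rises of this comparison, ehd2.S, rilp.S, tmem169.L and itgb1bp2.L, lay between 2.43 and 2.79, sag.L rose by at least 2.13, and the other falls, bola2.L, gdpd1.L, gtf2ird1.S and agr2.L, between -2.75 and -2.40. TFAP2A knockdown changed 3677 of 32539 probe sets, 11.3%, with 1724 higher and 1953 lower, and 8927 had an unadjusted p under 0.05. Of 11303 genes, 555 rose and 837 fell. The count was 697 without Control MO replicate 1, 7 without Control MO replicate 2, 658 without TFAP2A MO1/2 replicate 1 and 81 without TFAP2A MO1/2 replicate 2. Among the 7 were chit1.S, sun2.L and selenok.S, with changes of 3.27, 3.77 and -3.62 there.

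In TFAP2A knockdown caps, the keratin gene krt12.5.S fell by 2.16 ± 0.14 (adjusted p = 0.00594), and 4 of 29 keratins fell, with 5 down adjusted over the list alone. The envoplakin gene evpl.L fell by 1.30 ± 0.12, the plakophilin gene pkp3.S by 0.89 ± 0.13 and itga6.L by 0.99 ± 0.21 among 13 desmosome and hemidesmosome genes, and 3 fell adjusted over the list alone. In the adherens junction list of 23, nectin1.L fell by 1.52 ± 0.25, the E-cadherin gene cdh1.S by 1.43 ± 0.26 and jup.S by 0.55 ± 0.12, with 4 down adjusted over the list alone. Of 26 epidermal transcription factors 4 fell, both copies of tp63 by 1.37 ± 0.16 (tp63.L) and 1.33 ± 0.24 (tp63.S), and klf17.L and klf17.1.S by 0.82 ± 0.15 and 0.68 ± 0.14, with 3 up and 8 down adjusted over the list alone. Of 28 tight junction genes, cldn6.2.S rose by 0.73 ± 0.15, and limma called 0 adjusted over the list alone, with 8 at an unadjusted p under 0.05. In the polarity list of 19, pard3.S rose by 1.11 ± 0.18 and lin7c.L fell by 1.24 ± 0.20, with 2 up and 3 down, and 3 up and 4 down adjusted over the list alone. None of these 6 lists was called, with adjusted p between 0.150 and 0.958, and 0 of the 7 calls left without Control MO replicate 2 were genes of this paragraph.

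**Figure D2:**
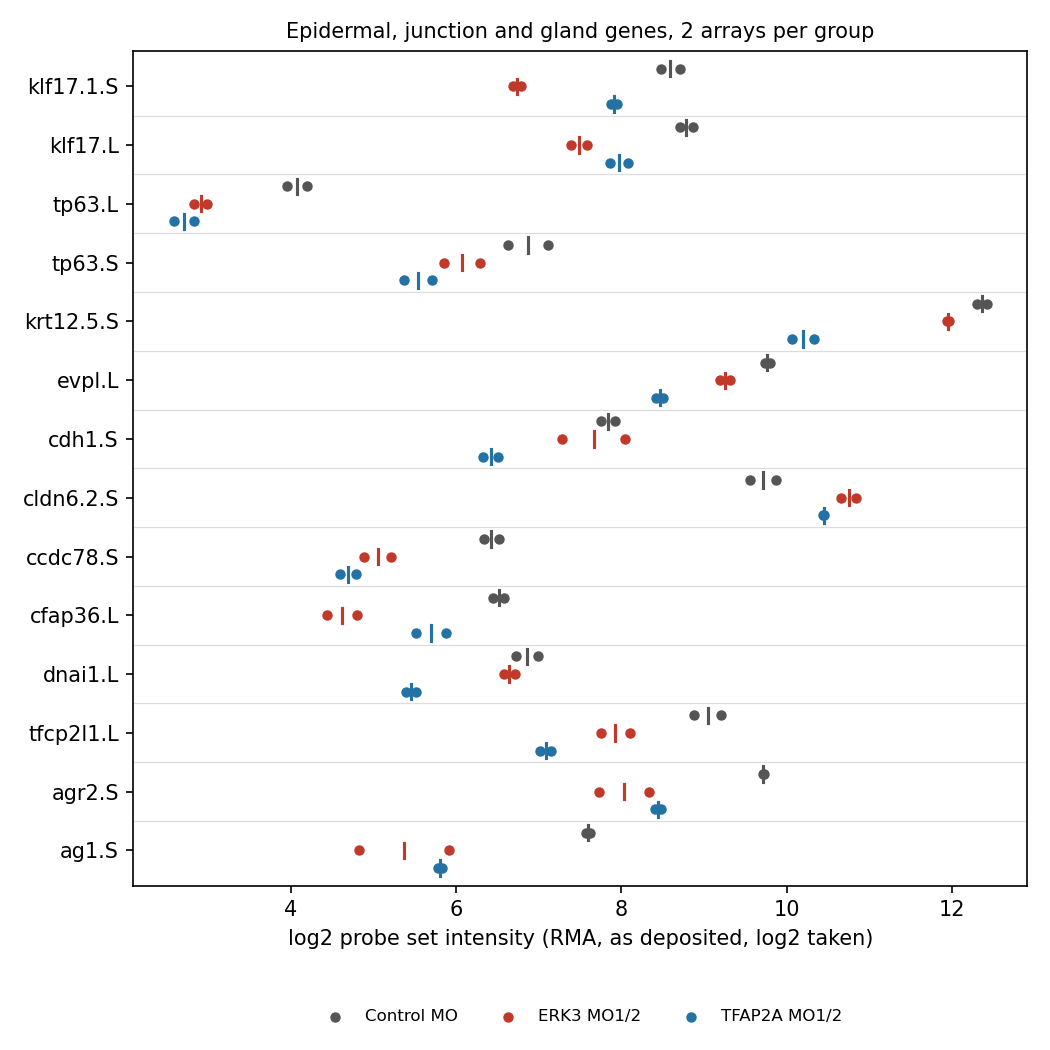
Log2 probe set intensity on the x axis for epidermal, junction, cilia and gland genes, with 1 point per array, 2 arrays per group, and a bar at each group mean. The control arrays lie above the arrays of both knockdowns for tp63.L, ccdc78.S and agr2.S, and below them for cldn6.2.S.

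Of 57 multiciliated cell genes, 9 fell, 1 rose and 47 did not pass in TFAP2A knockdown caps, and 16 fell and 1 rose adjusted over the list alone. The falls of ccdc78.S, cfap300.L, the axonemal dynein gene dnai1.L and cfap20.L were 1.73 ± 0.16, 1.48 ± 0.25, 1.41 ± 0.14 and 0.98 ± 0.16 in size. The list's median change was -0.49 (camera adjusted p = 1.39e-06), with an adjusted p = 0.969 with an estimated correlation. It was -0.76 without TFAP2A MO1/2 replicate 1 and -0.30 without TFAP2A MO1/2 replicate 2, where the list was still called. Of 9 cement and hatching gland genes, 5 fell, also adjusted over the list alone, with a median of -1.27 (camera adjusted p = 0.0083, and adjusted p = 0.969 with an estimated correlation). They were agr2.L, agr2.S, ag1.S, the hatching enzyme family gene astl2d.1.L, which fell by 2.34 ± 0.42, and crx.S. That list's call was lost without Control MO replicate 2, at 0.0815. Of 43 ionocyte genes, 6 fell and 1 rose, also adjusted over the list alone, and tfcp2l1 fell in both copies, by 1.96 ± 0.18 (tfcp2l1.L) and 1.27 ± 0.15 (tfcp2l1.S). Of 18 goblet and small secretory genes 3 fell, both copies of agr2 and the calpain gene capn8.1.L, and 4 fell adjusted over the list alone. The gene calls of this paragraph were lost without Control MO replicate 2.

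Of 49 neural genes, the geminin gene gmnn.L, which restrains DNA replication, fell by 1.37 ± 0.14 and otx2.S fell by at least 0.69 in TFAP2A knockdown caps. Of 29 neural crest and placode genes, pax3.L fell by 0.92 ± 0.15 and sox8.L by 0.69 ± 0.12. Of 70 mesoderm and endoderm genes, both copies of mix1 rose, mix1.S by at least 0.40 and mix1.L by 0.75 ± 0.14, and fgf8.L and actc1.L fell by 1.11 ± 0.20 and 1.64 ± 0.35. Adjusted over the list alone, 2 neural and 2 crest and placode genes fell, and 2 mesoderm and endoderm genes rose and 1 fell. The adjusted p of these 3 lists was 0.419, 0.124 and 0.958, and the gene calls were lost without Control MO replicate 2.

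The list of FGF/MAPK response and immediate early genes was called lower in TFAP2A knockdown caps, with a median of -0.53 (camera adjusted p = 0.0229), and was not called with an estimated correlation (adjusted p = 0.969) or by fry (0.278). Of 30 genes, 4 fell and 26 did not pass, and 5 fell adjusted over the list alone. The immediate early gene btg2.S fell by 2.43 ± 0.54, the MAP kinase phosphatase genes dusp1.S and dusp1.L by 1.80 ± 0.41 and 0.80 ± 0.14, and the pathway inhibitor gene spred1.L by 0.94 ± 0.17. The list's call was lost without TFAP2A MO1/2 replicate 1 (0.0656) or Control MO replicate 2 (median -0.34, 0.166). The change of dusp1.S was -1.16 without Control MO replicate 2. In ERK3 knockdown caps, 4 of the 30 fell and 1 rose, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.163). There spred1.L fell by 1.06 ± 0.17, the serum response factor gene srf.L by 1.27 ± 0.26 and ier2.S by 0.60 ± 0.13, while the phosphatase gene dusp5.S rose by 0.80 ± 0.14, calls that ended without either control array. In the direct contrast, dusp5.S was higher in ERK3 knockdown caps by 0.78 ± 0.14, and 3 genes were higher adjusted over the list alone (camera adjusted p = 0.419).

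The genes changed by both knockdowns were led by rpe65.L, cxcl12.L, pou5f3.3.L, sun2.L and itgb1bp2.L, which rose in both. The rise of sun2.L was 2.55 ± 0.23 with ERK3 MO1/2 and 3.46 ± 0.23 with TFAP2A MO1/2, and that of rpe65.L was at least 4.36 and 2.17. The falls in both were led by mgst1.L, agr2.L, slc2a12.L, selenok.S and rbm12.L. The glucose transporter gene slc2a12.L fell by 2.17 ± 0.36 in each, and selenok.S by 0.71 ± 0.14 with ERK3 MO1/2 and 3.59 ± 0.14 with TFAP2A MO1/2. The other probe set of selenok.S changed by -0.22 with ERK3 MO1/2 and -2.13 with TFAP2A MO1/2. Of all probe sets, 1554 were called in both in the same direction, 675 higher and 879 lower, and 26 in opposite directions. Independent lists of these sizes would share 77.4 higher and 119.0 lower. Simulated unchanged groups with shared simulated control arrays, which hold next to no calls, shared a mean of 0.04. In 100 simulated sets of that kind, the called changes of each knockdown were laid on independently drawn probe sets. These shared a mean of 180.4 in the same direction, at most 211. Both expectations spread the calls evenly over all probe sets. At or above the median level alone, 3129 and 3276 probe sets were called and 1419 shared, so both expectations may be too low. These 1554 made up 45.1% of the ERK3 calls and 42.3% of the TFAP2A calls.

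Of the ERK3 calls, 90.0% had the same sign in TFAP2A knockdown caps, beside 85.3% among as many of the smallest p-values of unchanged groups and 54.5% with the called changes laid on independent probe sets. Across probe sets, which are not independent replicates, the log2 changes had a correlation of 0.657 beside 0.502 in the simulation. Their covariance was 0.176 beside 0.0246, a difference of 0.151. The 2 control arrays could not be split into parts of 2, so part of the excess in shared calls may come from the shared controls, although the covariance was 0.1365 and 0.1457 with 1 control array for each knockdown. The shared count was 0 without Control MO replicate 1 and 0 without Control MO replicate 2, where ERK3 MO1/2 had 0 limma calls with 7287 and 6539 probe sets at an unadjusted p under 0.05. It was 172 and 831 without ERK3 MO1/2 replicates 1 and 2, and 361 and 49 without TFAP2A MO1/2 replicates 1 and 2.

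**Figure D3:**
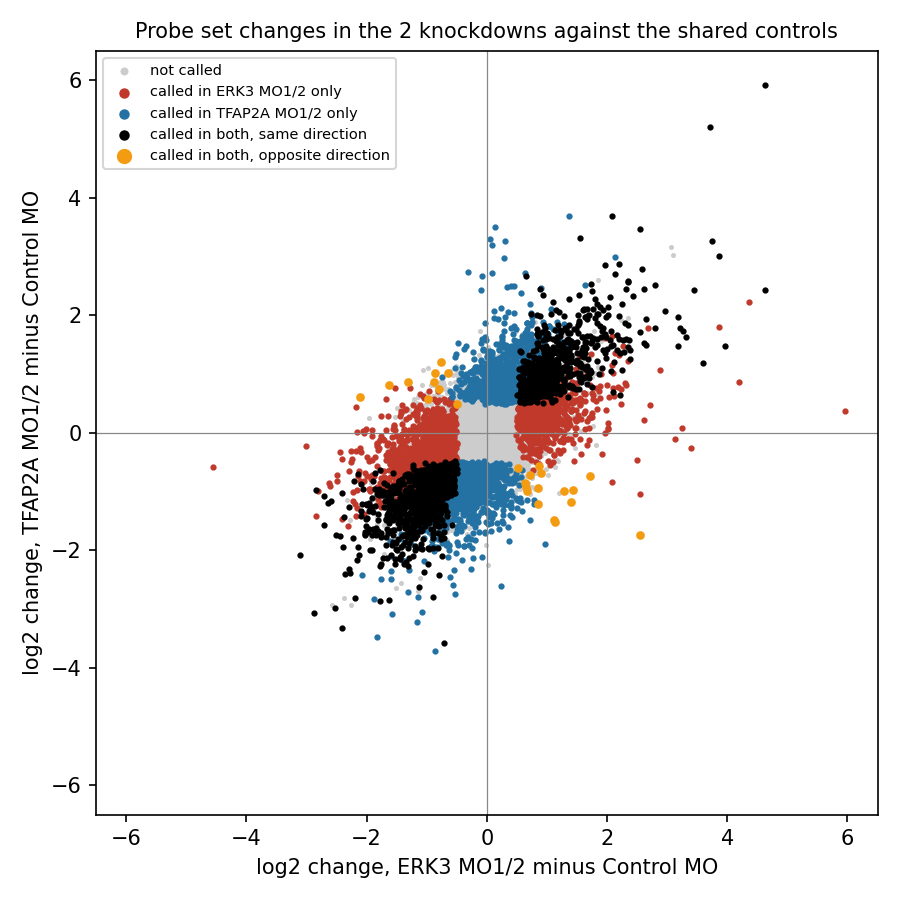
Log2 change of each probe set with ERK3 MO1/2 on the x axis and with TFAP2A MO1/2 on the y axis, both against the same 2 control arrays, coloured by where it was called. The 1554 probe sets called in both in the same direction lie in the upper right and lower left, and the 26 called in opposite directions in the other corners.

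Set directly against each other, ERK3 knockdown caps had higher tspan4.S than TFAP2A knockdown caps, at least 8.02-fold (limma adjusted p = 0.00184), and higher selenok.S, hal.2.L and gpx1.S, by 2.88 ± 0.14, 2.48 ± 0.27 and 2.41 ± 0.25. They had lower wfdc2.L, by -3.97 ± 0.47, lower chit1.S, by -3.25 ± 0.12, and lower tdrd12.L, a gene of the piRNA pathway. Some genes were called in opposite directions against Control MO. The calcium sensor gene vsnl1.L rose by 1.39 ± 0.20 with ERK3 MO1/2 and fell by 1.18 ± 0.20 with TFAP2A MO1/2. The kinetochore gene nuf2.L fell by 2.10 ± 0.12 with ERK3 MO1/2 and rose by 0.60 ± 0.12 with TFAP2A MO1/2. The mesoderm gene tbxt.L was lower in ERK3 than in TFAP2A knockdown caps, with a difference of -2.61 ± 0.44 (adjusted p = 0.0337). Its intensities were 66.8 and 32.3 in control caps, 10.3 and 10.3 in ERK3 knockdown caps, and 89.6 and 44.0 in TFAP2A knockdown caps.

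The direct contrast called 1552 probe sets, 4.77%, with 741 higher and 811 lower in ERK3 knockdown caps, and 6727 had an unadjusted p under 0.05. Of 1863 ERK3 calls that were not TFAP2A calls, 549 differed directly between the knockdowns, as did 592 of 2097 TFAP2A calls that were not ERK3 calls and 94 of the 1554 shared calls. Without ERK3 MO1/2 replicate 1, limma called 0 probe sets, with 5405 at an unadjusted p under 0.05, and without ERK3 MO1/2 replicate 2 it called 54. Without either TFAP2A array it called 1, Xl2.55361.1.A1_at, which was higher in ERK3 knockdown caps, and without either control array it called 295.

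In the direct contrast, the cell cycle and DNA replication list was called lower in ERK3 knockdown caps, with a median of -0.18 (camera adjusted p = 0.0327), and was not called with an estimated correlation (adjusted p = 0.969) or by fry (0.195). Of 83 genes, 7 were lower, 3 higher and 73 did not pass, with 11 lower and 4 higher adjusted over the list alone. The mitotic phosphatase gene cdc25c.L differed by -1.59 ± 0.15, the mitotic kinase genes aurkb.L and ttk.S by -1.53 ± 0.14 and -1.15 ± 0.16, and the spindle motor gene kif11.S by -0.94 ± 0.12. The list's call was lost with cyclic loess (adjusted p = 0.0663) and without ERK3 MO1/2 replicate 1 (0.128) or TFAP2A MO1/2 replicate 2 (0.111). Against Control MO, 11 of the 83 fell and 3 rose with ERK3 MO1/2, and 14 and 5 adjusted over the list alone, with cdc25c.L down by 2.00 ± 0.15. With TFAP2A MO1/2, 5 fell and 7 rose, 5 and 10 adjusted over the list alone, and the replication helicase gene mcm5.S fell by 1.57 ± 0.14 while the mitotic gene birc5.L rose by 1.57 ± 0.19. This list was not called against Control MO, with adjusted p of 0.341 and 0.419.

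Epidermal genes that differed directly included krt12.5.S, higher in ERK3 knockdown caps by 1.75 ± 0.14, evpl.L, higher by 0.79 ± 0.12, and klf17.1.S and tbx2.S, lower with differences of -1.17 ± 0.14 and -0.87 ± 0.16. Of 57 multiciliated cell genes, dnai1.L and foxj1.2.L were higher by 1.20 ± 0.14 and 1.10 ± 0.19, and cfap36.L and cfap45.L lower, and 3 were higher and 5 lower adjusted over the list alone. Of 43 ionocyte genes, tfcp2l1.S was higher by 0.98 ± 0.15 and atp6v0d1.L and ca12.L were lower, with 2 higher and 4 lower adjusted over the list alone. Of 70 mesoderm and endoderm genes 6 were lower, with 9 adjusted over the list alone, among them gata4.S and gata4.L with differences of -1.59 ± 0.21 and -1.02 ± 0.12. Among neural genes gmnn.L was higher and tubb2b.S lower, and among crest and placode genes sox8.L and ets1.S were lower, the same 1, 1 and 2 as adjusted over the list alone. Limma called 0 genes of the tight junction, polarity, adherens junction, goblet and small secretory, and cement and hatching gland lists, with 2, 8, 3, 1 and 3 at an unadjusted p under 0.05, and 1 adjusted over the list alone, a polarity gene. Adjusted over the list alone, 1 desmosome gene was higher and 1 lower, 2 keratins were higher and 1 lower, and 1 epidermal transcription factor was higher and 2 lower. These lists had adjusted p between 0.107 and 0.958, and the gene calls were lost without ERK3 MO1/2 replicate 1 and without either TFAP2A array.

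**Figure D4:**
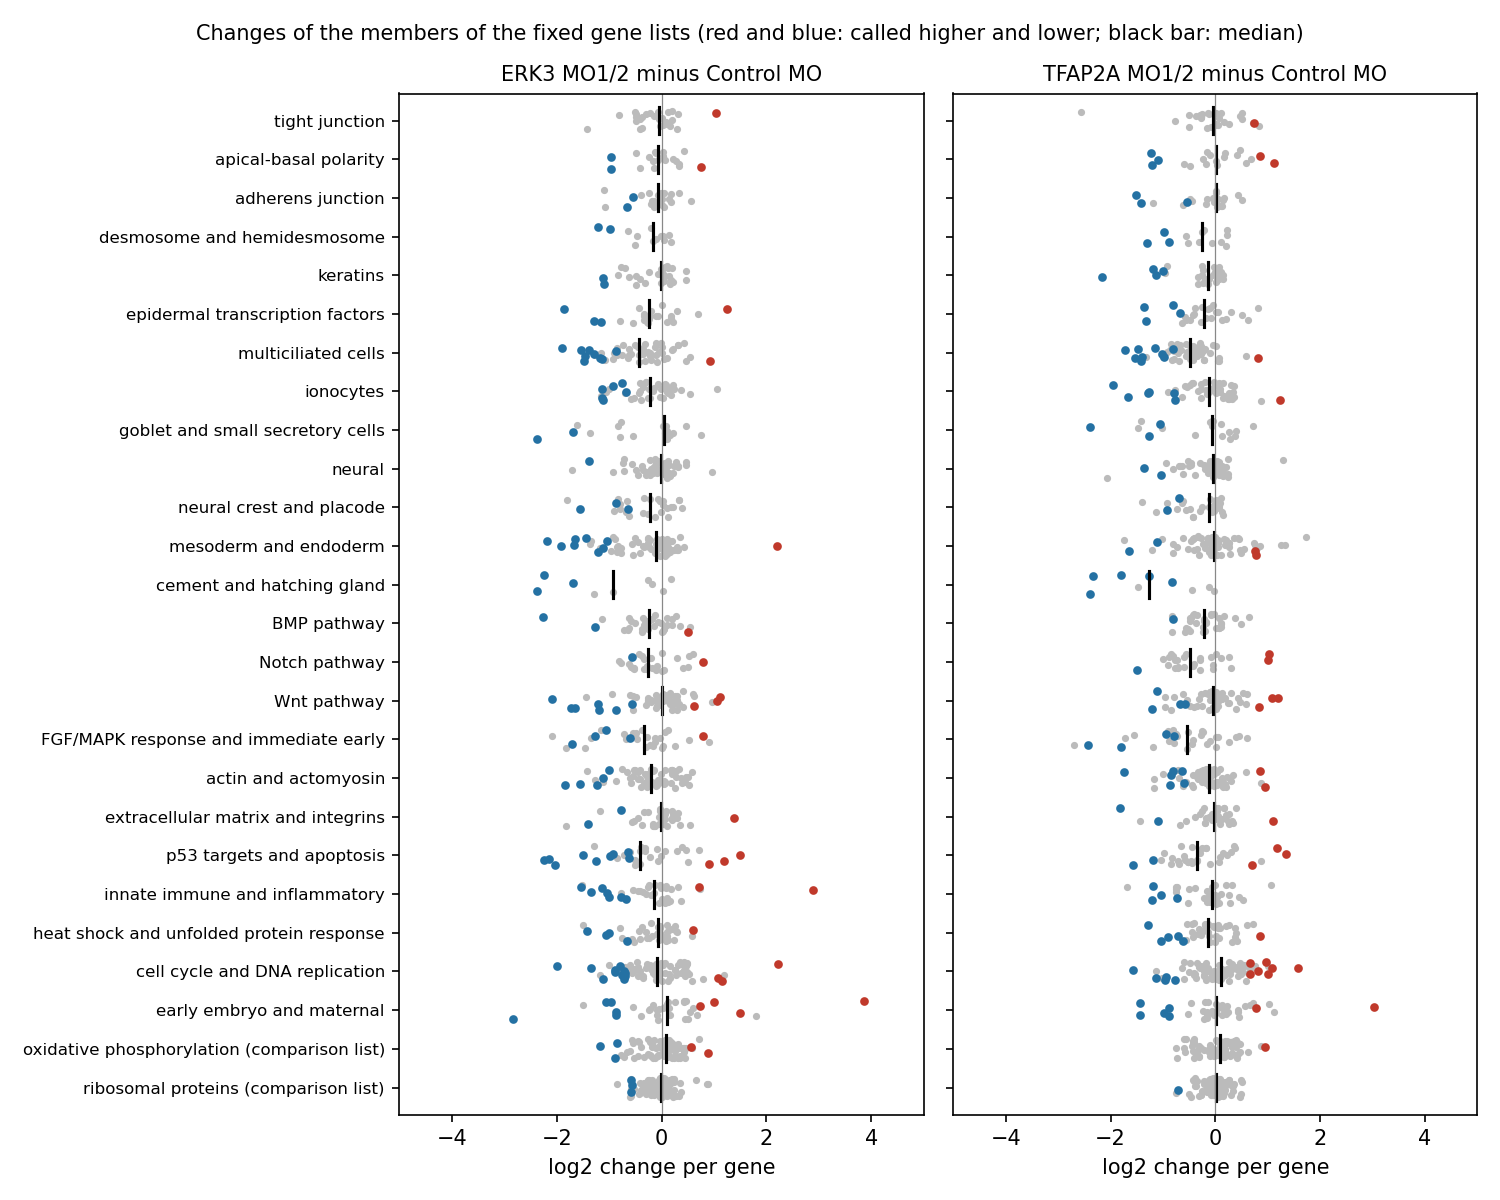
Log2 change per gene on the x axis for the members of the 26 fixed gene lists, with ERK3 MO1/2 on the left and TFAP2A MO1/2 on the right, red and blue for genes called higher and lower, grey for the others and a black bar at each list's median. The median of the multiciliated cell list lies at -0.43 with ERK3 MO1/2 and at -0.49 with TFAP2A MO1/2.

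Some named genes had further probe sets. Of 72 named calls of such genes, 34 had another probe set called in the same direction, and 0 had one that limma called in the opposite direction. Among the 34 were calls of ppl.L, actn1.L, ag1.S and tp63.S, and those of selenok.S with TFAP2A MO1/2 and in the direct contrast. In 20, among them itga6.L, gata4.L and top2a.L, another probe set had a change of the opposite sign that did not pass. Not all of these were dim. The other probe set of id4.S, at a log2 level of 6.75, changed by 0.39 with ERK3 MO1/2. That of nrarp.S, at 6.62, changed by 0.2 with TFAP2A MO1/2. Of the 40 named largest rises and falls against Control MO, 12 had the other copy measured, which lay at or above the median level for 5 and was dim for 7, with ehd2.L standing in both comparisons. Of these 5, fam3a.L and agr2.S were called in the same direction, with -0.85 and -1.27, and rpe65.S, gpx1.L and gapdh.S, with -0.51, -0.12 and -0.11, did not pass. None of the dim copies, such as ehd2.L, atp12a.S and hal.2.S, was called. The sign of the median, the mean and the test of a list differed for 4 lists with ERK3 MO1/2, 4 with TFAP2A MO1/2 and 3 in the direct contrast, and 0 of these were called by camera; 0 of 26 lists were called with an estimated correlation or by fry in any comparison, where 0 lists with an estimated correlation and 8, 9 and 2 by fry had an unadjusted p under 0.05.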

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

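The test that averaged the L and S copies of a gene was chosen after seeing the data, and the other alternatives were planned. Replicate numbers are shared between groups, and the labels do not say that a number marks a shared clutch or day. With the replicate number as a block, 7945, 7934 and 4831 probe sets were called for ERK3 MO1/2 minus Control MO, TFAP2A MO1/2 minus Control MO and the direct contrast, and 4179 were shared, against 3443, 3677, 1552 and 1554 without it. As a check of this pairing, the difference between replicates 2 and 1 correlated across probe sets, which are not independent replicates, by 0.535, 0.545 and 0.595 between groups. The lowest of these was 0.543 after cyclic loess, which argued against intensity-dependent differences between arrays. Bright probe sets of the same gene correlated by 0.474 over 2230 pairs. This argued against noise of single probe sets only as far as the pairs share no probes, which was not checked. A shared clutch or day was not tested. Leaving out 1 array without the block sets 1 replicate number against the mean of both. Part of the shared deviation then enters the changes of that group, so calls lost there do not measure noise alone. A 2-fold minimum left 1609, 1692, 804 and 637, because it adds a condition, and an adjusted p under 0.1 gave 5995, 6129, 3146 and 2979, because it is a wider threshold. Fits of the 2 groups compared alone, with fewer arrays behind the spread, called 2002, 3000 and 295. Trend and robust settings, cyclic loess and probe sets at or above the median level kept all 4 counts within 1.5 times. Leaving out each array in turn gave 0 to 2002, 7 to 3000, 0 to 295 and 0 to 831; a group left with 1 array adds nothing to the spread, and that array is assumed to vary like the others. By limma, the counts of 0 had 7287, 6539 and 5405 probe sets at an unadjusted p under 0.05. Of 5 called lists, 0 were called with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by fry (19 at an unadjusted p under 0.05), 10 lists were called at or above the median level, 3 with L and S copies averaged, and 3 to 16 with 1 array left out. The cell cycle list in the direct contrast was also lost with cyclic loess (median -0.15, adjusted p = 0.0663), at or above the median level (0.071) and with the mean over probe sets (0.0564). The FGF/MAPK list with TFAP2A MO1/2 was lost at or above the median level (0.11) and with copies averaged (0.179), as was the cement and hatching gland list with copies averaged (0.109). For these, the cause was not tested. Both multiciliated cell lists were called in all other alternatives that were run on lists. With ERK3 MO1/2 the list only just passed without Control MO replicate 2, at a median of -0.34. Of 261 calls of named genes, 0 changed sign with the block, trend and robust settings, cyclic loess, the mean over probe sets or 1 array left out. The block ended 0 of these calls, trend and robust settings 8, cyclic loess 5 and the mean over probe sets 25, and leaving out 1 array between 95 and 241. Signal over background limits the dim end: the lower quartile of intensity on the linear scale was 6.36 to 6.96 over the arrays, where a fall has little room and the size of a rise is only a bound, and no detection call was used.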

Other observations

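The use of the planned p53 and early embryo lists as tests of an explanation, and the tests of independently laid changes, of other probe sets of a gene and of bright homeologues were chosen only after the results were seen. In ERK3 knockdown caps, 9 of 34 p53 target and apoptosis genes fell and 3 rose, 12 and 5 adjusted over the list alone, with the cell cycle inhibitor gene cdkn1a.L down by 2.24 ± 0.25, sesn1.L down by 1.49 ± 0.19 and the stress gene gadd45g.L up. In TFAP2A knockdown caps 2 fell and 3 rose, also adjusted over the list alone, with rrm2b.S down by 1.57 ± 0.22. Of 35 innate immune genes 7 fell and 2 rose with ERK3 MO1/2, 7 and 3 adjusted over the list alone, and 4 fell with TFAP2A MO1/2, also adjusted over the list alone; the receptor gene tlr5.L fell with both, by at least 0.35 and 0.40. Of 42 heat shock and unfolded protein response genes 4 fell and 1 rose with ERK3 MO1/2, 5 and 1 adjusted over the list alone, and 5 fell and 1 rose with TFAP2A MO1/2, also adjusted over the list alone. The chaperone gene calr.L fell by 1.05 ± 0.12 with ERK3 MO1/2 and sdf2l1.L by 1.29 ± 0.12 with TFAP2A MO1/2. Of 35 early embryo and maternal genes 4 rose and 5 fell with ERK3 MO1/2, 5 and 5 adjusted over the list alone, and 2 rose and 5 fell with TFAP2A MO1/2, 4 and 5 adjusted over the list alone; pou5f3.3.L rose most, by 3.86 ± 0.22 and 3.02 ± 0.22. Among comparison lists, 2 of 80 oxidative phosphorylation genes rose and 3 fell with ERK3 MO1/2, 0 and 1 adjusted over the list alone (23 at an unadjusted p under 0.05), and 1 rose with TFAP2A MO1/2, 0 adjusted over the list alone by limma (20 at an unadjusted p under 0.05). Of 97 ribosomal protein entries 3 fell and 1 fell, with 0 adjusted over the list alone (16 and 15 at an unadjusted p under 0.05); both counts hold rps6kb1.L, an S6 kinase gene taken in by its name. Directly between the knockdowns, cdkn1a.L was lower with ERK3 MO1/2, by -1.78 ± 0.25, and rrm2b.S and mdm4.S were higher, cebpb.L was lower, sdf2l1.L was higher and ddit4.S and hspa4.L were lower, the same counts as adjusted over each list alone. There 3 early embryo genes were higher and 3 lower, 9 and 8 adjusted over the list alone, atp5mc1.S was lower and cox7a2l.L higher, as adjusted over the list alone, and rpl34.S was lower, with limma calling 0 adjusted over the list alone (11 at an unadjusted p under 0.05). None of these lists was called by camera, with adjusted p between 0.11 and 0.991, and of the gene calls those for ERK3 MO1/2 ended without either control array and those for TFAP2A MO1/2 without Control MO replicate 2.

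Among signalling and structure genes, 7 of 53 Wnt pathway genes fell and 3 rose with ERK3 MO1/2, 8 and 4 adjusted over the list alone, and 4 fell and 3 rose with TFAP2A MO1/2, also adjusted over the list alone. The planar polarity gene vangl1.L fell by 2.08 ± 0.19 and 1.21 ± 0.19, and the Wnt antagonist gene dkk1.S by 1.64 ± 0.18 and 1.12 ± 0.18. Of 35 BMP pathway genes, id2.S and id4.S fell by 2.25 ± 0.24 and 1.27 ± 0.14 with ERK3 MO1/2 and ventx1.1.L rose, with 2 down adjusted over the list alone, and id4.S fell by 0.80 ± 0.14 with TFAP2A MO1/2, also adjusted over the list alone. Of 28 Notch pathway genes, maml1.L rose by 0.79 ± 0.14 and esr-5.L fell with ERK3 MO1/2, and with TFAP2A MO1/2 lfng.S and maml1.L rose, by 1.01 ± 0.12 and 1.01 ± 0.14, and nrarp.S fell by 1.49 ± 0.20, the same counts as adjusted over the list alone. The other probe set of id4.S with ERK3 MO1/2, and that of nrarp.S with TFAP2A MO1/2, had the opposite sign and did not pass. Of 63 actin and actomyosin genes 5 fell with ERK3 MO1/2, also adjusted over the list alone, and 6 fell and 2 rose with TFAP2A MO1/2, 7 and 2 adjusted over the list alone; the alpha-actinin gene actn1.L fell by 1.84 ± 0.12 and 1.75 ± 0.12. Of 38 extracellular matrix and integrin genes, col1a2.L rose by 1.39 ± 0.16 and timp-1.L and itga3.L fell with ERK3 MO1/2, and itgb5.L rose by 1.09 ± 0.13 and itga3.L and col18a1.L fell with TFAP2A MO1/2, itga3.L by 1.82 ± 0.16, the same counts as adjusted over the list alone. Directly between the knockdowns, fzd8.S was lower and wif1.S higher with ERK3 MO1/2 (2 and 2 adjusted over the list alone), id2.S was lower, nrarp.S higher and lfng.S lower, and col1a2.L and itga3.L higher, also adjusted over each list alone. Of the actin list, 4 were lower there, tpm4.L by -1.36 ± 0.17, and 1 higher, 5 and 3 adjusted over the list alone. These lists had adjusted p between 0.113 and 0.945, and their gene calls against Control MO ended without Control MO replicate 2, those for ERK3 MO1/2 also without Control MO replicate 1. The direct calls of this and the former paragraph ended without ERK3 MO1/2 replicate 1 and without either TFAP2A MO1/2 array.

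Both knockdowns changed many of the same probe sets in the same direction, 1554 in all. Noise particular to single control arrays was argued against as the whole cause. With each knockdown set against a different control array, the covariance of log2 changes was 0.1365 and 0.1457, above the simulated 0.0246. Changes laid on independent probe sets, drawn evenly over all levels, shared at most 211. Both simulations drew noise independently between arrays, without the deviation that same-numbered arrays shared. A difference common to both control arrays stays in both comparisons and was not tested. Morpholino toxicity with p53 activation would raise the p53 target list. The median change of that list was below 0, at -0.407 with ERK3 MO1/2 (camera p = 0.0589 with an estimated correlation) and -0.35 with TFAP2A MO1/2 (p = 0.109). Its members went both ways. The test asked for p under 0.05 with an estimated correlation, which 0 lists reached in any comparison. It could therefore not decide, and p53 activation stays open. Slower development in both knockdowns was put to the same kind of test, which could not decide it either. The medians of the early embryo list, 0.113 and 0.019, lay near 0 over members that went both ways. A common action of ERK3 and TFAP2A on the ectoderm is a further hypothesis and was not tested apart from these.

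Large changes were smaller at the other homeologue of a gene, which, where bright, had the same sign in 78.1% of pairs with ERK3 MO1/2 and 80.1% with TFAP2A MO1/2 and was called the same way in 36.1% and 29.1%. Probe sets were assigned to a copy by annotated symbol alone, and whether their probes tell the L and S copies apart was not checked. The first copy was chosen as called and at least 2-fold and the partner was not, so that choice alone lowers the ratio. The same choice was made for other probe sets of a gene, and whether these share probes was not checked. A pair with both copies so changed was counted from each copy, which the intervals do not allow for. Signal particular to single probe sets was judged by a bound for the lower end of an interval, set after the results were seen. It was argued against for ERK3 MO1/2, where another bright probe set of the gene had a median ratio of changes of 0.68 (95% bootstrap interval 0.54 to 0.77, 120 pairs, 51.7% called the same way), and 0.77 (0.52 to 1.07, 24 pairs) in genes that also have a bright homeologue. The rule asked for a lower end above the bound in both sets of pairs. With TFAP2A MO1/2 the 104 pairs met it, at 0.77 (0.66 to 0.85, 63.5% called the same way). Genes that also have a bright homeologue did not, at 0.90 (0.29 to 1.03, 19 pairs). The test could therefore not decide for TFAP2A MO1/2, and signal particular to single probe sets stays open there. It also stays open for the direct contrast, at 0.57 (0.43 to 0.65) and 0.66 (0.35 to 1.16), and for the named largest changes with a measured partner, whose genes have 1 probe set each, apart from gapdh.L, since the gapdh control probe sets also read lower. A partner too dim to show a change was argued against where both copies were at or above the median level, since the ratio of the partner was 0.40 (0.31 to 0.51, 155 pairs) and 0.38 (0.33 to 0.48, 141 pairs) against Control MO. In genes that have both kinds of partner, the homeologue had 0.39 (0.23 to 0.51, 24 pairs) with ERK3 MO1/2. With TFAP2A MO1/2 it had 0.41 (0.13 to 0.68, 19 pairs), which overlaps the interval of their other probe sets, 0.29 to 1.03. A dim partner stays open for the direct contrast, at 0.31 (0.17 to 0.44), and where the partner was under the median level. Sequence differences between clutches at single copies may contribute and stay open, with a median ratio of 0.15 (0.01 to 0.39, 27 pairs) between replicate numbers, which the labels do not tie to clutches, as does different regulation of the L and S copies, which was not tested.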
